A study of Mus musculus with 6 samples.

How the data were processed

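RNA was taken from the anterior palatal mesenchyme of mouse embryos at E12.5 after the epithelium had been removed with Dispase II, per the labels' protocols. The 6 libraries were 3 of wildtype embryos and 3 of embryos in which Wnt1Cre, a recombinase active in neural crest cells, acts on a floxed Meis2 allele. The labels call the 3 samples of each genotype biological replicates. RNA was purified with RNeasy Micro Plus, reverse transcribed and amplified, and libraries were made with TruSeq RNA v2, per the labels' protocols. Amplification before library preparation can add noise to genes with few reads. HISAT2, featureCounts and DESeq2 are named in the submitters' processing notes, with the builds GRCm38 and mm10. Their versions and settings, and whether counting used strand, are not given in the sources used here. Without that setting, reads of overlapping or antisense genes cannot be told apart.

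The data were 3 tables of the authors' own comparison, with no values per library. Each row gives a gene symbol and 6 values from DESeq2, as deposited by the authors. The base mean is a signal that is never negative, the mean of counts divided by size factors, as deposited by the authors. The fold change and its standard error are on the log2 scale in the deposited tables. The Wald statistic is a score with no fixed range, deposited by the authors. The p-value and the Benjamini-Hochberg adjusted p-value are those of the authors' DESeq2 Wald test, as deposited. The fold changes are moderated, that is drawn toward 0 most strongly for genes with few reads. The 1236 genes with a single read in all libraries have an absolute log2 fold change of at most 0.006, and the highest standard error is 0.150. Fold changes of weakly expressed genes are therefore understated.

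The series' design text describes each table as a wildtype and a mutant library of the same number, and the tables hold something else. A gene with a single read in all libraries has a base mean fixed by the size factor of the library that holds the read. In the first table such genes take 6 levels of base mean (tolerance 2e-06), 3 with a positive and 3 with a negative fold change, so the table rests on 6 libraries, 3 against 3. The second table holds 4 of these levels, 2 on each side, and lists the single-read genes of the other 2 libraries at 0. It has reads for 0 genes that the first table lacks, while the first has reads for 570 genes that the second lacks. The second table therefore compares 4 of the same 6 libraries, and which replicates it leaves out is not known. The third table holds 1613 rows, each equal to a row of the first, and these are the 1613 rows of the first table with a p under 0.05. It adds no measurement. The search for levels was tested on simulated counts of 6 libraries over 20997 genes and found 6.

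A limma test across 3 independent pairs had been planned. With nested tables it would have treated the same libraries as separate, so it was replaced by the adjusted p of the authors' 6-library DESeq2 comparison, with genes called at an adjusted p under 0.05. The 4-library table was used as an alternative that leaves out 1 library of each genotype, an alternative chosen after the data were examined. The sign of the fold change is not named in the sources used here. It was read as mutant over wildtype because Meis2, the deleted gene, is lower under that reading, a rule set before the data were examined. Every direction given here rests on that reading.

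Size factors read from the single-read levels ran from 0.775 to 1.44 over the 6 libraries, a ratio of 1.86. Base means summed to 15317259 in the 6-library table and 16869001 in the 4-library table. The tables list 24421 rows each, with 3424 and 3994 genes at a base mean of 0, and 14942 and 14548 genes with an adjusted p. The 6-library table has 27 rows with names that a spreadsheet had turned into dates. These were not named.

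The 25 gene lists and the rule for named genes were fixed before the data were examined. List members with a base mean of at least 10 count as measured, among 14580 such genes in the 6-library table. Lists with at least 3 measured members, 22 in all, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald scores. The inter-gene correlation was preset at 0.01, and p was adjusted by Benjamini-Hochberg over the 22 lists. This test compares a list with the other genes. An estimated correlation needs values per library, so a preset of 0.05 was tried in its place. On shuffled Wald scores of 14577 genes, a shift of -2 in the osteogenic list and of 2 in the muscle list was called in 100% of 50 draws, and a shift of 1 in the Wnt list in 78%. Lists left alone were called in 1.63% of 800 tests. Shuffling removes the correlation between list members, so this rate need not hold for lists whose members vary together. For each list the p-values of its members were also adjusted over the list alone.

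Named genes were Meis2, the 10 largest rises and the 10 largest falls among called genes, and up to 4 members of each developmental list with the largest absolute fold change. All had a base mean of at least 50 and the same direction in both full tables, and predicted genes were skipped, which gave 54 genes. Some genes that meet this rule or belong to a list are counted but not reported here by name. Other genes are named as called members of a list or as counterparts in a comparison, chosen after their values were seen. Coordinates and genomic lengths were taken from annotation of GRCm38 by symbol, with a length for 99.6% of the genes with a base mean of at least 10, and GC content of the longest transcript from GENCODE vM21 for 96.2%. Further lists of 31 muscle and 30 neuron genes, which share no gene with the first lists, were written after the first lists had been tested and before these genes' values were looked at. The median of a random list was drawn 10000 times among genes of similar base mean. Intervals of medians are 95% bootstrap intervals over genes, which cover the choice of genes and not the spread between embryos. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

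Alternatives tried were base mean minimums of 100 and of none, a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, fold changes centred on their median, and, added after the data were examined, the 4-library table, a correlation of 0.05 and removal of the trend with genomic length. Fold changes were not recomputed from reads.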

Results

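Meis2 is a homeodomain transcription factor of the TALE class, and the design asks how the transcriptome of the anterior palatal mesenchyme differs when it is deleted by Wnt1Cre, which is active in the neural crest that forms most of this tissue. RNA-seq was made from 3 wildtype and 3 Wnt1Cre;Meis2f/f samples at E12.5. The authors' deposited tables give 1 comparison of all 6 libraries and 1 of 4 of these libraries, 2 per genotype. Values are from the 6-library table unless the 4-library table is named. Fold changes are mutant over wildtype and moderated toward 0, so those of weakly expressed genes are understated. Size factors of the 6 libraries ran from 0.775 to 1.44, and the base means, which are mean normalised read counts, summed to 15317259. Of that sum the ribosomal RNA gene Rn45s took 14.0%, the mitochondrial leucyl-tRNA synthetase gene Lars2 2.83% and the nuclear RNA Malat1 1.88%, in the authors' deposited table. With 4 libraries these shares were 17.4%, 3.81% and 1.61%. The libraries left out thus held smaller shares of Rn45s and Lars2 on average. The comparisons of 6 and of 4 libraries therefore differ in library composition as well as in the number of libraries.

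Meis2 (chromosome 2, 115861264 to 116067537, GRCm38) had a log2 fold change of -0.28 (SE 0.092), or 0.825 of the wildtype level, in the authors' deposited table. Its adjusted p of 0.0743 (DESeq2 Wald test) missed the threshold in the authors' deposited table. In the authors' deposited table of 4 libraries the log2 fold change was -0.33 (SE 0.093), with an adjusted p of 0.0213. The sign of the tables was read from this gene, so its direction is not an independent check of the genotypes, and every direction given here rests on that reading. The part of the gene that is deleted is not given in the sources used here, and transcripts that lack it would still be counted.

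Transcripts of 434 genes differed between the genotypes at an adjusted p under 0.05 in the authors' deposited table (DESeq2 Wald test), 261 of them higher and 173 lower in the mutant. Among these, 26 had an absolute log2 fold change of at least 1, with 18 higher and 8 lower. The largest fall among named genes was that of Unc5d, a netrin receptor (chromosome 8, 28646717 to 29219671), with a log2 fold change of -1.27 (SE 0.107, adjusted p 1.62e-28) in the authors' deposited table. Pcp4, a calmodulin regulator, fell by 1.14, Pdzrn4 by 1.10, Sytl5 by 1.08 and Aldh1a2, which makes retinoic acid, by 1.04 on the log2 scale in the authors' deposited table. Falls of 1.01 for Cpm, 0.96 for Alx4, 0.91 for Col25a1, 0.91 for the histone variant gene H2afv and 0.90 for Shox2 completed the 10 named falls. Among the rises, Tmem132b had a log2 fold change of 1.50 (SE 0.131, adjusted p 8.40e-27), or 2.82-fold, in the authors' deposited table. Cemip, which acts in the breakdown of hyaluronan, rose by 1.43, the prokineticin receptor gene Prokr2 by 1.37 and Cilp by 1.36 on the log2 scale in the authors' deposited table. Brinp3 (1.32), Trhde (1.26), Vstm2a (1.22), Ptprq (1.18) and the forkhead gene Foxd1 (1.14) were other log2 rises. In the authors' deposited table of 4 libraries the log2 values of Tmem132b and Pcp4 were 0.67 and -0.64, both still called. H2afv has a near-identical paralog, H2afz, with which its reads can be confused. No library carries Cre alone, so neither the fall of H2afv nor any other difference given here can be told apart from an effect of the Wnt1Cre transgene.

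**Figure D1:**
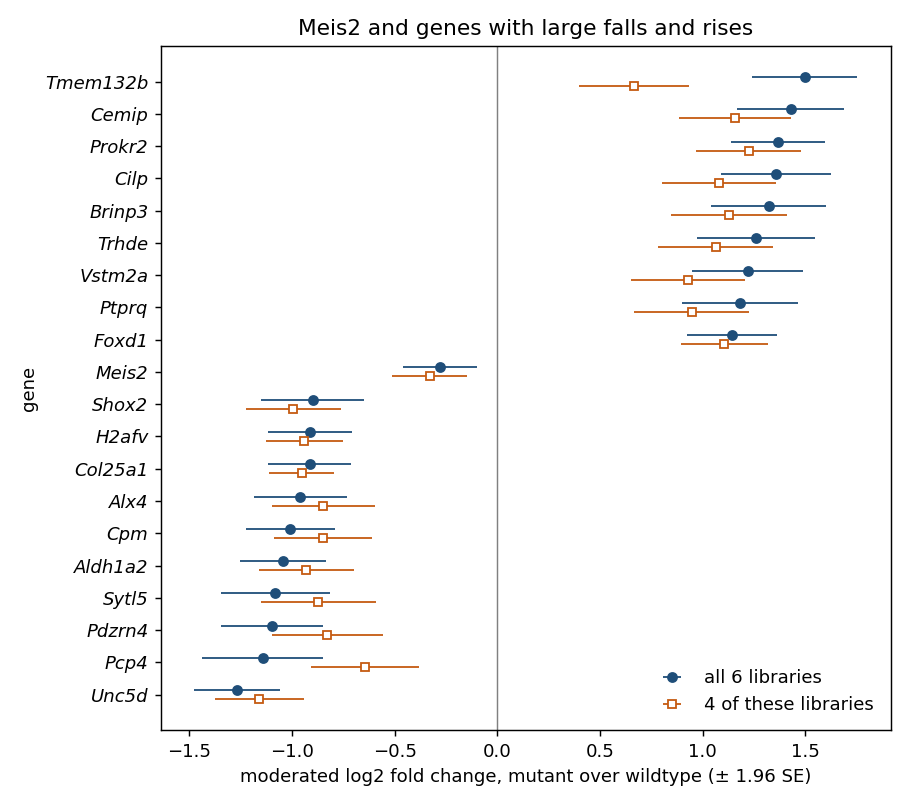
Log2 fold changes (mutant over wildtype, moderated, x axis) of Meis2 and of genes with the largest falls and rises that are named in the text (y axis) in the authors' deposited tables of all 6 libraries (filled circles) and of 4 of them (open squares), with bars for 95% intervals from the deposited standard errors. Values run from -1.27 for Unc5d to 1.50 for Tmem132b with 6 libraries, and Tmem132b and Pcp4 lie nearer 0 with 4.

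Genes of bone formation were lower in the mutant as a group. Of 27 measured members of the osteogenic list, 7 fell, 0 rose and 20 did not pass the test, and adjusted over the list alone 9 fell and 0 rose, in the authors' deposited table. The median log2 fold change was -0.24 (95% interval -0.32 to -0.10), with 23 members below 0, and the list test gave an adjusted p of 2.34e-10 (cameraPR). Bmp2, a bone morphogenetic protein, fell by 0.82 (SE 0.143, adjusted p 1.82e-06), and Runx2, the transcription factor required for osteoblast formation (chromosome 17, 44495987 to 44814797), by 0.64 (adjusted p 9.30e-06) on the log2 scale in the authors' deposited table. Bmp3, Msx2, Twist1 and Postn also fell, by 0.55, 0.55, 0.45 and 0.40. Of these, Bmp3 antagonises BMP signalling, Twist1 restrains osteoblast differentiation and Postn encodes a matrix protein of periosteum and other connective tissue. Alpl, Col1a1 and Sp7, which mark differentiating osteoblasts, had log2 fold changes of -0.36, -0.32 and -0.30 and adjusted p of 0.171, 0.395 and 0.465 in the authors' deposited table. In the authors' deposited table of 4 libraries 4 of the list's members were called, and Runx2, Bmp3 and Msx2 were not, at -0.33, -0.36 and -0.27 with adjusted p of 0.321, 0.175 and 0.245. Markers of muscle were higher and of neurons lower in the same comparison, with median log2 fold changes of 0.49 and -0.49.

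Some cartilage genes also fell. Of 14 measured members of the chondrogenic list 3 fell and 0 rose, adjusted over the list alone 5 fell and 0 rose, and the median log2 fold change was -0.09, and -0.02 with 4 libraries, in the authors' deposited table. Col9a1, a cartilage collagen gene, fell by 0.78, Matn4, a matrilin gene, by 0.69 and Fgfr3 by 0.46 (adjusted p 0.0406) on the log2 scale in the authors' deposited table. Sox9, the transcription factor required for cartilage formation, had a log2 fold change of -0.35 and an adjusted p of 0.0738 in the authors' deposited table. The list test gave an adjusted p of 0.0148 (cameraPR), and adjusted p = 0.0566 with a preset correlation of 0.05. Fgfr3 lost its call with 4 libraries, where its log2 fold change was -0.27 and its adjusted p 0.551 in the authors' deposited table, and Sox9 gained one at 0.0125. Col9a2, another cartilage collagen gene, had a log2 fold change of 0.26 and was not called with 6 libraries, but rose with 4, by 0.38 (adjusted p 0.0270), in the authors' deposited table.

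Genes known for expression in the anterior palate went both ways. Of the 13 measured, 4 fell and 3 rose, and adjusted over the list alone 5 fell and 3 rose, in the authors' deposited table. Shox2, a homeobox gene of the anterior palate (chromosome 3, 66971723 to 66981771), fell by 0.90 (SE 0.127, adjusted p 4.36e-10), and the aristaless-like gene Alx4 (chromosome 2, 93642434 to 93681341) by 0.96 on the log2 scale in the authors' deposited table. Inhba, which encodes the activin A subunit, fell by 0.50, and Pax3 and Alx1 rose by 0.67 and 0.66 on the log2 scale in the authors' deposited table. Pax3 lost its call with 4 libraries, at a log2 fold change of 0.42 and an adjusted p of 0.0927 in the authors' deposited table. The list test gave an adjusted p of 0.0756 over 13 genes, and 0.00278 with the 4-library table (cameraPR). Of 7 measured members of the posterior palate list 2 fell and 0 rose, Col25a1 and the T-box gene Tbx3, by 0.91 and 0.54 on the log2 scale in the authors' deposited table, with the same 2 calls adjusted over the list alone. The posterior list had a median log2 fold change of 0.03 while its test pointed lower (adjusted p 0.0291, cameraPR), and adjusted p = 0.0566 with a preset correlation of 0.05 and 0.0571 among genes with a base mean of at least 100. With 4 libraries the posterior median was -0.06 and the list test's adjusted p 2.58e-04, and with the length trend removed the adjusted p was 0.0157. Meox2 and Barx1, both of the posterior palate, had log2 fold changes of 0.15 and 0.17 and were not called in the authors' deposited table.

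Among 22 measured genes of the general palate patterning list, 7 fell and 4 rose, and adjusted over the list alone 8 fell and 9 rose, in the authors' deposited table. The homeobox genes Gsc and Lhx6 fell by 0.77 and 0.60, and the zinc finger homeobox gene Zfhx4 by 0.61 on the log2 scale in the authors' deposited table. Hand2, Tbx2, Prrx1 and Lhx8 also fell, by 0.58, 0.40, 0.31 and 0.29, while Foxd1 rose by 1.14, Pax9 by 0.46, Foxp1 by 0.45 and Nr2f2 by 0.45. The list as a whole had an adjusted p of 0.831 (cameraPR). Of 12 measured TALE genes and partners, Pbx3, a binding partner of Meis proteins, fell by 0.46 and Irx5 by 0.53, and Pknox2 rose by 0.55 on the log2 scale in the authors' deposited table. Meis1, the closest relative of Meis2, had a log2 fold change of 0.27 and was not called in the authors' deposited table. Adjusted over the list alone 2 TALE genes rose and 3 fell, with a median of 0.02 (-0.01 with 4 libraries), a test that pointed lower and an adjusted p of 0.545. Irx5, Pknox2 and Nr2f2 lost their calls with 4 libraries, at log2 fold changes of -0.30, 0.37 and 0.38 and adjusted p of 0.377, 0.194 and 0.0538, and Hand2 kept its call at a log2 fold change of -0.29, in the authors' deposited table.

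Signalling genes changed individually, and none of the 4 signalling lists passed its test. Of 35 measured Wnt genes 5 rose and 4 fell, and adjusted over the list alone 6 rose and 6 fell, in the authors' deposited table (list test, adjusted p 0.272). Rspo2, a secreted enhancer of Wnt signalling, rose by 0.84 (SE 0.109, adjusted p 4.44e-12) while its relative Rspo3 fell by 0.49 (SE 0.089, adjusted p 3.68e-06) on the log2 scale in the authors' deposited table. The secreted Wnt inhibitor genes Dkk1, Wif1, Sfrp1 and Dkk2 rose by 0.67, 0.51, 0.44 and 0.41, and Wnt16, Wnt11 and Dkk3 fell by 0.71, 0.49 and 0.42 on the log2 scale in the authors' deposited table. Of 26 measured BMP and TGF-beta genes 3 fell and 2 rose, and adjusted over the list alone 3 fell and 3 rose (list test, adjusted p 0.505, pointing lower with a median log2 fold change of 0.005, and -0.002 with 4 libraries), in the authors' deposited table. Bmp2, the BMP target Id2 and the BMP antagonist gene Chrdl1 fell by 0.82, 0.59 and 0.46, and Tgfbr3 and Tgfb2 rose by 0.42 and 0.42. Of 16 measured hedgehog genes 1 rose and 0 fell, with the same count adjusted over the list alone: Hhip, an inhibitor of hedgehog ligands, by 0.67 on the log2 scale in the authors' deposited table (list test, adjusted p 0.505). Foxl1, Foxf2 and Gas1 of this list had log2 fold changes of 0.28, -0.18 and -0.25 and were not called in the authors' deposited table. Of 17 measured FGF genes Fgf7 and Fgfr3 fell, by 0.55 and 0.46, adjusted over the list alone 4 fell and 0 rose, and the list test gave an adjusted p of 0.132, in the authors' deposited table. Etv4 and Etv5, transcriptional targets of FGF signalling, were both at -0.35 and not called in the authors' deposited table. With 4 libraries Dkk1, Wif1, Dkk3, Chrdl1, Tgfb2 and Fgf7 were no longer called, at adjusted p of 0.0769, 0.218, 0.191, 0.139, 0.175 and 0.366 in the authors' deposited table. Their log2 fold changes there were 0.44, 0.37, -0.32, -0.40, 0.32 and -0.30, so that Dkk1 and Fgf7 moved by over 1.5 times and the others by less. Wnt16 kept its call at a log2 fold change of -0.43 with 4 libraries in the authors' deposited table.

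Cell cycle genes were lower by a small amount as a group. The list mixes genes that drive the cycle with the inhibitor genes Cdkn1a, Cdkn1b, Cdkn1c and Cdkn2c. These inhibitor genes had log2 fold changes of 0.23, -0.17, -0.12 and -0.27. The median log2 fold change of 33 measured cell cycle genes was -0.17 (95% interval -0.26 to -0.13), 32 of them lay below 0, and the list test gave an adjusted p of 3.97e-08 (cameraPR), in the authors' deposited table. No single member was called over all genes (DESeq2 Wald test, 0 of 33), 10 fell and 0 rose adjusted over the list alone, and 12 were lower and 0 higher at an unadjusted p under 0.05 in the authors' deposited table. With 4 libraries 4 members fell, Top2a and Ccna2 among them, with log2 fold changes of -0.30 and -0.35 in the authors' deposited table. Markers of muscle, neurons and macrophages had medians of 0.49, -0.49 and 0.24 in the same comparison. The immediate early and the hypoxia and glycolysis lists, 16 measured genes each, had 0 called members over all genes or over the list alone (DESeq2 Wald test), and 0 and 2 at an unadjusted p under 0.05, in the authors' deposited table. Their list tests gave adjusted p of 0.831 and 0.132.

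Markers of other cell types differed between the genotypes by type. All 18 measured muscle markers lay above 0 in the authors' deposited table, 11 rose, 16 rose adjusted over the list alone, and the median log2 fold change was 0.49 (95% interval 0.33 to 0.56; list test, adjusted p 4.10e-20). Myog, a transcription factor of muscle differentiation, rose by 0.70, and Tnnt1, a troponin of muscle fibres, by 0.83 on the log2 scale in the authors' deposited table. All 11 measured neuron markers lay below 0 in the authors' deposited table, 6 fell, also adjusted over the list alone, and the median was -0.49 (95% interval -0.66 to -0.13; list test, adjusted p 3.24e-11). Tubb3, a neuronal tubulin, fell by 0.68 and Dcx, a microtubule protein of migrating neurons, by 0.66 on the log2 scale in the authors' deposited table. With 4 libraries these medians were 0.28 and -0.18, with 4 muscle markers and 2 neuron markers called, and Tubb3 was not among them at -0.33 and an adjusted p of 0.314, in the authors' deposited table. Macrophage markers were higher, with 3 of 13 called, Csf1r, Mrc1 and Adgre1, also adjusted over the list alone, and a median of 0.24 (list test, adjusted p 4.59e-05) in the authors' deposited table. With 4 libraries the median was 0.16, and Adgre1 lost its call at 0.29 with an adjusted p of 0.451, in the authors' deposited table. Schwann cell and glial markers were lower, with a median of -0.17 over 11 genes (-0.07 with 4 libraries), Ngfr called and 4 lower adjusted over the list alone (list test, adjusted p 0.0021), but with 4 libraries the adjusted p was 0.168 for the list test and 0.175 for Ngfr, whose log2 fold change went from -0.38 to -0.32, in the authors' deposited table. None of the 23 epithelial, 16 endothelial and 7 erythroid markers was called over all genes or over the list alone (DESeq2 Wald test), and 1, 0 and 2 had an unadjusted p under 0.05, in the authors' deposited table. Their median log2 fold changes were 0.02, 0.02 and 0.04 with 6 libraries and 0.06, 0.03 and -0.004 with 4, with adjusted p of 0.689, 0.689 and 0.612 in their list tests. The erythroid list holds 12 genes, and its globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had a base mean of 0 with 6 and with 4 libraries. The erythroid result therefore rests on a list without these globin genes. Of 7 pericyte markers 1 rose, Des, which the muscle list also holds (list test, adjusted p 0.505), and its log2 fold change went from 0.47 to 0.13 (adjusted p 0.773) with 4 libraries in the authors' deposited table. The forebrain list had 1 measured member and the Hox list 0, so neither was tested.

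**Figure D2:**
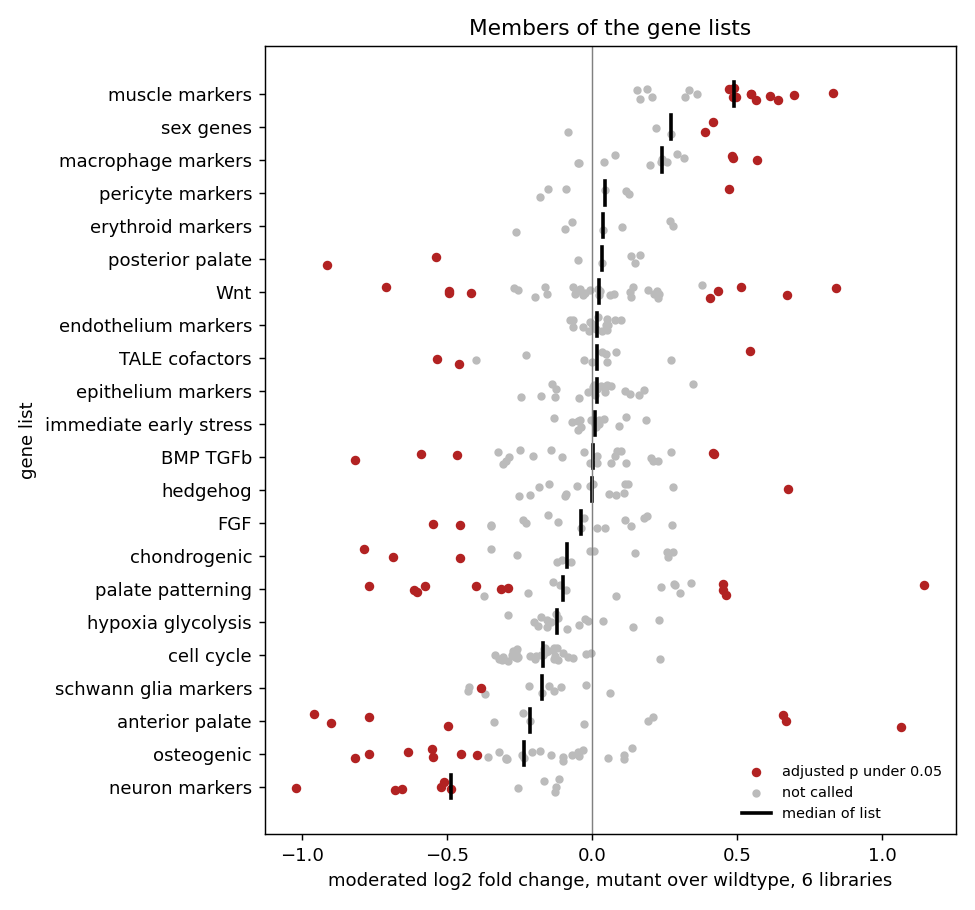
Log2 fold change (mutant over wildtype, moderated, 6 libraries, x axis) of each measured member of the 22 tested gene lists (y axis, ordered by median) from the authors' deposited table, red where the adjusted p was under 0.05 and grey otherwise, with a black bar at the list's median. Medians run from -0.49 for neuron markers to 0.49 for muscle markers, and the osteogenic list lies second from the bottom at -0.24.

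The comparison of 4 libraries shares all of its libraries with that of 6, so it is no independent replicate. Over 14467 genes with a base mean of at least 10 in both of the authors' deposited tables, the log2 fold changes had a Pearson r of 0.93 and a Spearman rho of 0.92 across genes, which are not independent replicates, and 87.9% had the same sign. Simulated libraries with no effect, nested in the same way, gave an r of 0.81 and 80.1% with the same sign. The covariance was 0.0232, beside 0.0112 in the simulation scaled to the deposited standard errors. Both tables called 165 genes higher and 96 lower, and 0 genes in opposite directions, among 14524 genes. Lists of these sizes taken from the ends of simulated comparisons with no effect, nested in the same way, shared 95.1 and 62.8 genes on average over 100 draws, and at most 110 and 75. Independent lists with no library in common would share 3.43 and 1.71. Part of the overlap comes from the shared libraries, and neither value allows for both shared libraries and real effects.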

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

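Tests with the 4-library table, the correlation of 0.05 and the length trend removed were chosen after the results were seen; the others before. No paired analysis was possible because the tables hold no values per library and do not compare same-numbered libraries. For the same reason leaving out each replicate, fits without the replicate block, trended or robust empirical Bayes fits, other count models and scalings, pseudocounts, an estimated inter-gene correlation, fry and other splits of the 6 samples were not run. The count of 434 called genes stayed within 1.5 times under a stricter adjusted p (305), base mean minimums of 100 (345) and of none (414), centring (458), the 4-library table (335) and the length trend removed (434), and was 26 with an absolute log2 fold change of at least 1. In the 4-library table it was 218 at the stricter adjusted p and 8 with that fold change, and 8 genes had both calls with it. The share with the same sign was 86.9% with no filter. Meis2 passed the threshold at -0.33 in the 4-library table and at -0.33 with the length trend removed, and at -0.26 when centred it had an adjusted p of 0.103. Among the lists, the chondrogenic adjusted p was 0.0566 at the correlation of 0.05, that of the anterior palate 4.73e-05 with a base mean of at least 100 and 0.00278 with 4 libraries, that of the posterior palate 0.0571 and 0.0566 with that base mean and that correlation, and that of Schwann cells and glia 0.168 with 4 libraries. The cause was not tested. All 22 lists kept their side of the threshold with the length trend removed. Of the 53 named genes besides Meis2, 42 kept their side in the 4-library table, 10 lost the call and 1 gained it, and 52 kept it when centred or with the length trend removed, Fgfr3 being the exception at 0.0513 and 0.0809. Depth limits genes with few reads, whose fold changes are moderated most.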

Other observations

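The tests of the difference between muscle and neuron markers, of the size of the further marker lists, of the neighbours of H2afv and of the transgene were chosen after the result was seen. Among genes outside the named ones, Neb, which encodes a giant protein of muscle thin filaments, rose by 1.07 (0.55 with 4 libraries) and Crabp1, which binds retinoic acid in the cell, fell by 0.48 on the log2 scale in the authors' deposited table, both chosen after their values were seen. The Y-linked genes Uty and Kdm5d rose by 0.42 and 0.39, while Xist, expressed from the inactive X chromosome, was at -0.08 and not called in the authors' deposited table. Ddx3y and Eif2s3y, also Y-linked, were at 0.22 and 0.27 and not called. The sex gene list had a median log2 fold change of 0.27 over 5 measured genes, with 4 higher adjusted over the list alone and an adjusted p of 0.0021 in its test (cameraPR). This list pools Xist with Y-linked genes, so its direction has no plain meaning. In the authors' deposited table of 4 libraries Xist fell by 0.38 and 4 Y-linked genes rose. The sex of the embryos is not given in the sample labels, so for these genes sex cannot be told apart from genotype. Of 76 genes within 5 Mb of Meis2, 5 were called (6.58%, against 2.98% of all genes with a base mean of at least 10).

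Muscle markers were higher and neuron markers lower in the mutant libraries. A lower share of mesenchyme alone would raise both, and the lower neuron markers argue against it as the only cause. The medians lay 0.974 apart on the log2 scale (95% interval 0.566 to 1.15), and were 0.28 and -0.18 with 4 libraries. All 18 muscle markers lay above 0 and all 11 neuron markers below 0, so this interval had to exclude 0 and adds no support. Less mesenchyme would also raise endothelial markers, whose 16 measured members had a median of 0.018 (95% interval -0.009 to 0.050) and 0 calls. Macrophage markers went the other way, with a median of 0.24. The endothelial values argue against less mesenchyme as the source of a rise as large as that of muscle markers, unless endothelial cells were fewer too. A smaller loss of mesenchyme together with fewer neurons is not excluded. A larger share of muscle cells is a candidate explanation for the higher muscle markers. Outside the list and not looked at before, 24 further muscle genes had a median of 0.37 (95% interval 0.30 to 0.56), above 100% of random lists. Of these 24 genes 9 were called higher, and with 4 libraries their median was 0.255 and 4 were called. Random lists draw unrelated genes, while genes of a cell type can vary together between libraries, so ranks among random lists may overstate the evidence. These values cannot tell a larger share of muscle cells from higher expression per muscle cell. A smaller share of neurons is left open, since 19 further neuron genes had a median of -0.09 (95% interval -0.12 to -0.01), at the 0.39 percentile of random lists but nearer 0 than the first list's -0.49 (-0.66 to -0.13), with 0 called (DESeq2 Wald test; 2 lower and 1 higher at an unadjusted p under 0.05) and a median of 0.02 with 4 libraries. Whether such shares came from dissection or from the mutant embryos was not tested.

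H2afv (chromosome 11, 6427226 to 6444511, GRCm38) fell by 0.91 (SE 0.105) in the authors' deposited table. Reads moving to its paralog would raise H2afz, which was at -0.203 (95% interval -0.443 to 0.037). A fall shared by all genes of the region is argued against, since 14 other genes within 250 kb had a median of -0.0629 (95% interval -0.132 to 0.015). This median cannot exclude a change confined to the genes closest to H2afv. Its nearest listed neighbour, Ppia, was at -0.34 with an adjusted p of 0.0888, and 2.78e-04 with 4 libraries, in the authors' deposited table. Zmiz2 and Purb, the next nearest, were at -0.23 and -0.13 and not called in either table. An effect of the Wnt1Cre transgene cannot be told apart from the loss of Meis2, since no library analysed here carries Cre alone, and the fall was -0.939 with 4 libraries.

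Log2 fold change rose with genomic length (Spearman rho 0.193 across genes, which are not independent, and 0.166 with 4 libraries). It rose about as much with the length of the longest transcript (0.200, and 0.171 with 4 libraries), and these lengths were not told apart. Called genes were long in the genome, with medians of 97.7 kb among higher, 56.5 kb among lower and 22.9 kb among the rest. The longest quintile of genes held 150 of the higher and 74 of the lower calls. The trend is small, with a median log2 fold change 0.088 higher in the longest quintile than in the shortest. With it removed, 86.87% of the calls (377 of 434) stayed in the same direction, so a shift of this size does not account for most. Removal cannot show why called genes were long in both directions. GC content does not account for the trend, with a partial rank correlation with genomic length of 0.252 given GC content and base mean. More nuclear RNA, which is rich in introns, may contribute: 10 nuclear long noncoding RNAs had a median log2 fold change of 0.15, at the 99.99 percentile of random lists, though none was called singly (DESeq2 Wald test; 3 at an unadjusted p under 0.05). Of these RNAs Meg3, Rian and Mirg share a locus and Malat1 had been seen beforehand. The random lists were matched on base mean and not on length, so the length trend itself may add to this percentile. A biological dependence on length was not tested.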
